A study of Arabidopsis thaliana with 9 samples.

How the data were processed

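The series holds 9 one-colour Affymetrix arrays of biotin-labelled RNA from dark-grown Arabidopsis seedlings, 3 arrays for each of 3 lines. Per the labels' protocols, whole seedlings were frozen in liquid nitrogen, total RNA was extracted with a column kit, and labelled RNA was made with the Affymetrix IVT Express kit. The deposited table gives 1 intensity per probe set and array on a linear scale, for 22810 probe sets. GCOS is named in the submitters' processing notes as the software. The summary algorithm, the scaling target and detection calls are not given in the sources used here. The deposited intensity values were already scaled: the mean after trimming 2% at each end was 500.0 on all 9 arrays. No further normalization was applied in the main setting.

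Lines and replicate numbers came from the sample titles and sources. No 2 arrays held identical values, and no column of the table belonged to another sample. The labels do not say that a replicate number marks a shared batch, and the numbers were not treated as pairs. No slide or scan date was used.

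Signals were analysed as log2(signal + 16), which understates the change of genes with low signals. Between 16.5% and 21.3% of probe sets on an array lay under 16. The 64 control probe sets were left out, which left 22746. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 9 arrays with 3 lines and no block, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment over the 22746 probe sets. The threshold was an adjusted p under 0.05. Mean signals are given with their SD over 3 arrays, and log2 fold changes with the SE of the model. In tests on simulated data with 100 probe sets changed by a log2 of 1 and 100 by a log2 of 2 among 22746, the procedure recovered 37% and 84% in L17 against wild type, 40% and 89% in sps1 against wild type, and 46% and 87% in sps1 against L17. These simulations changed far fewer probe sets than were called in the data, with independent noise and no outlying array. The recovered shares may therefore differ in the real comparisons. The number of arrays limits the precision, and no depth applies to this kind of data.

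Genes were named from a platform annotation and from the RefSeq gene table of the assembly TAIR10.1, used for names and for the order of genes only. Of the tested probe sets 13513 name 1 gene, 503 name several, and 8730 are unnamed here. Of those naming 1 gene, 13436 matched the RefSeq table. PHYA and the other phytochromes were among the genes not named here, so the planned result on the PHYA level was not analysed. Probe sets naming several genes were not used for gene names or lists, and for a gene with several probe sets the one with the highest mean signal entered the lists.

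The comparisons were L17 against wild type, sps1 against wild type and sps1 against L17. The rule for named genes was set before the data were examined. It took, per comparison, the 10 largest rises and the 10 largest falls past the threshold with all 3 arrays of one line separate from the other and exactly 1 gene. It also took PHYA, genes with SPS in their names, up to 4 members of each discussed list with the smallest adjusted p, and the 10 shared genes with the largest smaller change. Genes of the third wild type array, of opposite changes and single members of lists that did not pass were named after their values were seen.

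Gene lists were also fixed before the data were examined. Of 29 lists, 15 had at least 3 members named here: light harvesting, nuclear photosystem with ATP synthase and Rubisco subunits, tetrapyrrole, flavonoid, auxin, gibberellin, cell wall loosening, dark-inducible genes, autophagy, beta-oxidation, root markers, dividing cells, abscisic acid and cold, plastid-encoded and mitochondrion-encoded. They were tested with limma's camera, which compares the members with all other named genes, at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether members move one way, were run beside it. Since many members were unnamed here, 18 further lists were written after the annotation had been seen and before any comparison of lines, and were adjusted separately. They appear among the additional observations.

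Overlap between the lines was set beside the overlap of independent lists, and the correlation and covariance of their changes beside 100 simulations of unchanged lines against the same wild type arrays. These simulations made almost no calls and so were not used for the shared counts. Alternatives were a replicate block, pseudocounts of 1 and 64, a filter on dim probe sets, quantile normalization, median centring, a trended and robust moderation, array weights, fits of 2 lines only, leaving out each array in turn, a fold threshold and a stricter adjusted p of 0.01. For lists they were the estimated correlation, fry and all probe sets of a gene. Calls of list members with each array left out, member counts and estimated correlations of lists without the third wild type array, the organelle medians without it, and the search for lists called under an alternative alone, were added after seeing the data.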

Results

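Transcript levels were measured in whole Arabidopsis thaliana seedlings that had grown in the dark for 10 days. Seedlings kept in the dark elongate and do not form green chloroplasts. There were 3 lines, each with 3 arrays: wild type of the accession Col-0, a line named L17 that the labels describe as a phyA' line, and a line named sps1. The labels give Col-0 as the background of all 3 lines and do not say what L17 or sps1 carries. PHYA encodes phytochrome A, a photoreceptor of seedlings in the dark. PHYA itself and the other phytochrome genes were not analysed here, because no probe set used here was named for them. The 9 arrays had median signals between 137.6 and 155, and their number limits the precision. The labels do not say whether arrays of a line came from separate plant batches, so the p-values measure only the spread between these arrays.

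The third wild type array stood apart from the other arrays. Its log2 signals correlated with those of the other wild type arrays at r = 0.954 across probe sets, which are not independent replicates, whereas those 2 arrays correlated at 0.986 with each other. They correlated at 0.956 to 0.965 with the L17 arrays and at 0.953 to 0.958 with the sps1 arrays, about as well as or better than with the third wild type array. On the third wild type array 2838 probe sets differed over 2-fold from the mean of the other 2 wild type arrays, 2146 of them upwards, while the corresponding numbers for the remaining 8 arrays lay between 440 and 1085. Small heat shock proteins, chaperones made under heat and other stress, had high signals there. AT2G29500 read 9140 on this array against 176.4 and 160.1 on the other wild type arrays, and AT1G53540 read 8199 against 146.9 and 128. None of the 6 arrays of the other lines exceeded 168.1 for AT2G29500 or 325 for AT1G53540. The ratio of 3' to 5' control probe sets for ubiquitin, a measure of how complete the RNA was, averaged 1.85 ± 0.0913 in wild type, 2.32 ± 0.103 in L17 and 2.49 ± 0.066 in sps1 (SD, n = 3). An exact two-sided permutation test gave p = 0.1 for either line against wild type, the smallest p that 3 against 3 arrays allow. The same ratio for actin averaged 2.65, 2.68 and 2.7, and for GAPDH 1.42, 1.58 and 1.7, in the same order of lines.

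**Figure D1:**
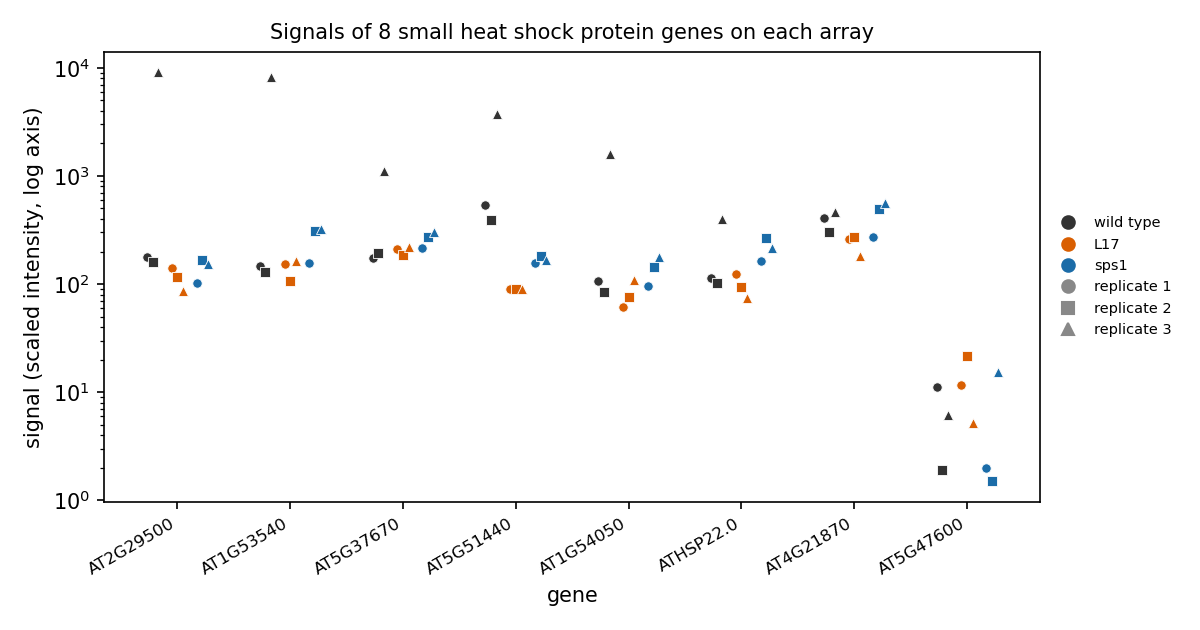
Signals of 8 small heat shock protein genes on each of the 9 arrays, on a log axis of scaled intensity. Points are single arrays, coloured by line and shaped by replicate, and the third wild type array read 9140 for AT2G29500 and 8199 for AT1G53540.

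In L17 the changes against wild type included genes that went from strong signal to almost none. AT5G45500 had a signal of 2089 ± 195 in wild type and 2.85 ± 1.81 in L17 (SD, n = 3), a log2 fold change of -6.80 ± 0.13 (SE, limma adjusted p = 9.46e-08). AT1G23960 went from 1949 ± 162 to 4.94 ± 4.22, a log2 fold change of -6.57. ZW9 fell from 3317 to 54.2, AT3G55790 from 818 to 1.85, and CYP71B34, a cytochrome P450, from 578 to 3.3. AT2G43590, of the chitinase family, fell from 2315 ± 640 to 62.8 ± 31.4. AT3G43740, AT3G47250, AT4G07820 and AT5G26270 completed the 10 largest falls, with log2 fold changes between -5.20 and -4.64. The largest rise at the pseudocount of 16 was that of GSTU23, a glutathione S-transferase, from 25.3 ± 8.79 to 928 ± 40.6, a log2 fold change of 4.54 ± 0.19 (SE, limma adjusted p = 5.60e-06). With a pseudocount of 1 AT1G31550, at 3.51 in wild type and 271 in L17, had a larger log2 fold change (5.91) than GSTU23 (5.19). AT2G40960 rose from 31.2 to 795, AT2G35820 from 142 to 2061, and PDF2.5, a plant defensin, from 40.4 to 615. AT4G04460, AT1G50290, AT1G31550, AT5G55360, AT1G52000 and AT5G41660 also stood among the 10 largest rises, with log2 fold changes between 3.19 and 3.83.

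Transcripts encoded in the plastid genome were the one fixed list that shifted in L17. Of its 69 measured members 29 rose, 1 fell and 39 did not pass the test, with a median log2 fold change of 1.01 (camera adjusted p = 7.33e-15). The call was lost when the correlation between members was estimated (adjusted p = 0.924 with an estimated correlation). Adjusted over the list alone, 47 members rose and 2 fell. The gene for a subunit of the plastid RNA polymerase, rpoC2, rose from 104 ± 26.1 to 986 ± 45.9, and psbA, for the D1 protein of photosystem II, from 145 ± 13.7 to 1113 ± 288. The genes rps18 and rpoA rose by 1.86 and 1.45 on the log2 scale. The ubiquitin 3' to 5' ratio was also higher in L17. A list of late embryogenesis abundant proteins, oleosins and cupins, written as markers of ungerminated seed, was lower (4 of 23 genes past the test, adjusted p = 0.392 with an estimated correlation, camera adjusted p = 0.142 without the first wild type array). The third wild type array had the lowest median of the plastid-encoded list, at -0.96 after each gene was centred, against -0.29 and -0.52 on the other wild type arrays. Without that array 23 members rose, 1 fell, and the median was 0.92 (camera adjusted p = 1.18e-11). The nuclear list of photosystem, ATP synthase and Rubisco subunits had no member past the test in L17 (0 of 6, camera adjusted p = 0.752).

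Single members of other fixed lists passed the test in L17. PORB, which reduces protochlorophyllide in chlorophyll synthesis, rose from 2043 ± 596 to 4576 ± 572, while HEMA2, an early enzyme of the tetrapyrrole pathway, fell from 360 ± 138 to 93.0 ± 7.51. In the light harvesting list LHCB4.2 fell by 1.15 and LHCB4.3 rose by 0.89 on the log2 scale. Of 9 cell wall loosening genes 2 rose and 1 fell, with log2 fold changes of 1.05 for XTH33, 0.71 for EXPA8 (adjusted p = 0.0594 without L17 replicate 3) and -0.70 for XTH16. The call of XTH16 was lost without the first or second wild type array (0.0734 or 0.0539) or L17 replicate 1, 2 or 3 (0.0732, 0.0766 or 0.0815). ATG8B of the autophagy list fell by 0.79, and the auxin response gene IAA29 gave 0.71, a call lost with any array left out (adjusted p between 0.0511 and 0.123). Of 45 called members of fixed lists 24 lost their call with at least 1 array left out, 9 of them without the third wild type array.

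In total 2601 of 22746 probe sets changed in L17 (limma adjusted p under 0.05), 1210 higher and 1391 lower, and 1249 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 5827. All 3 arrays of L17 lay on one side of all 3 wild type arrays for 31.2% of probe sets, where chance gives 10%. Without L17 replicate 1, 2 or 3 the number of changed probe sets was 1565, 1437 or 1628, and with only these 2 lines in the fit it was 1611. Without the third wild type array it was 2596, of which 2089 were among the 2601.

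**Figure D2:**
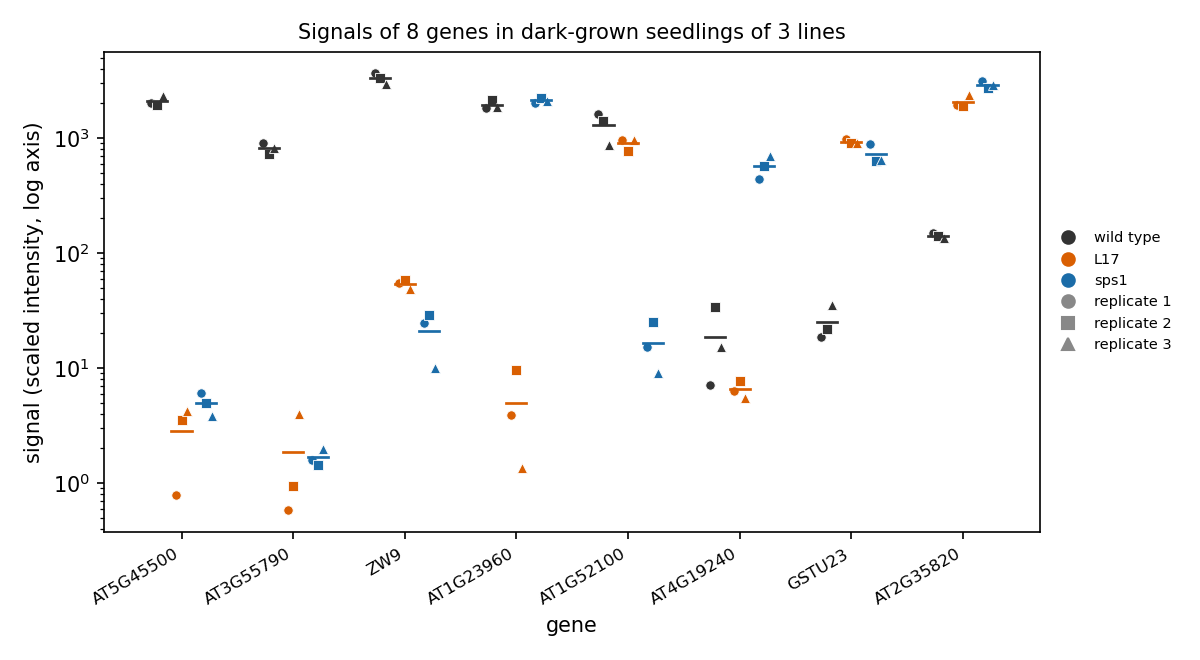
Signals of 8 genes taken from those with the largest changes, on a log axis of scaled intensity. Points are single arrays, coloured by line and shaped by replicate, bars are means over 3 arrays, and AT1G23960 read 1949 in wild type, 4.94 in L17 and 2122 in sps1 on average.

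In sps1 several of the same genes were nearly without signal. AT5G45500 read 4.95 ± 1.11 against 2089 ± 195 in wild type (SD, n = 3), a log2 fold change of -6.65 ± 0.13 (SE, limma adjusted p = 1.16e-07). ZW9 fell to 21.1 ± 9.85, AT2G43590 to 19.4 ± 3.47 and AT3G55790 to 1.67 ± 0.28. AT1G52100, of the jacalin lectin family, fell from 1303 ± 384 to 16.6 ± 8.22, AT1G72060, a peptidase inhibitor, from 6820 ± 1860 to 153 ± 31.7, and AT5G23830 from 1487 ± 799 to 24.0 ± 26.6. AT4G07820 and AT3G47250 fell by 5.03 and 4.95 on the log2 scale. AT1G26380, of the berberine bridge enzyme-like family, was also among the 10 largest falls, but its wild type mean of 3093 ± 4730 came mostly from the third wild type array, which read 8554 against 417.8 and 307.9. The largest rise at the pseudocount of 16 was that of AT1G50290, from 233 ± 64.3 to 5101 ± 279, a log2 fold change of 4.39 ± 0.21 (SE, limma adjusted p = 1.19e-05). AT2G35820 rose from 142 to 2919, GSTU23 from 25.3 to 721, AT4G19240 from 18.7 to 568 and AT5G20460 from 4.22 to 310. With a pseudocount of 1 the log2 fold changes of AT5G20460 (5.97), AT2G23480 (5.24), AT4G19240 (5.08), AT4G19730 (4.83), GSTU23 (4.81) and AT5G55360 (4.73) were larger than that of AT1G50290 (4.48). AT2G40960, AT5G55360, AT2G23480, AT4G19730 and AT5G18840 completed the 10 largest rises, with log2 fold changes between 3.46 and 3.82.

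Transcripts encoded in the plastid genome, and a nuclear list of photosystem, ATP synthase and Rubisco subunits, were higher in sps1, while the nuclear light harvesting list did not pass (1 of 3 members up, 1 down, camera adjusted p = 0.795). Of the 69 plastid-encoded transcripts 20 rose, 0 fell and 49 did not pass, with a median log2 fold change of 0.79 (camera adjusted p = 1.22e-11, and adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, 32 rose and 1 fell. The gene rpoC2 rose from 104 ± 26.1 to 806 ± 259, rps4 from 4218 ± 1040 to 14540 ± 583, and psbA and psaJ rose by 2.73 and 1.64 on the log2 scale. Without the third wild type array 16 rose and 0 fell, with a median of 0.54 (camera adjusted p = 1.57e-08). Of the 6 measured nuclear photosystem, ATP synthase and Rubisco genes 3 rose and 0 fell, with a median of 0.69 (camera adjusted p = 0.000331, and adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, all 6 rose. RCA, which activates Rubisco, rose from 3021 ± 322 to 6154 ± 330, PSBY from 2764 ± 574 to 6052 ± 258 and PSAE-1 from 2338 ± 480 to 3841 ± 53.3. The call of PSAE-1 was lost without the first or second wild type array, L17 replicate 1 or any sps1 replicate (adjusted p between 0.0643 and 0.111), and PSAN had a log2 fold change of 0.54 (limma adjusted p = 0.0531). The ubiquitin 3' to 5' ratio was higher in sps1 as well, and so was that of GAPDH (1.7 against 1.42 in wild type). The list written as markers of ungerminated seed was lower (10 of 23 past the test, adjusted p = 0.244 with an estimated correlation).

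Cell wall loosening genes, which encode expansins and xyloglucan endotransglucosylases, were lower in sps1. Of 9 measured members 4 fell, 1 rose and 4 did not pass, with a median log2 fold change of -0.87 (camera adjusted p = 0.0436, and adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, 5 fell and 2 rose. XTH16 fell from 1265 ± 170 to 469 ± 81.3, XTH18 from 1088 ± 494 to 336 ± 23, EXPB1 from 508 ± 112 to 254 ± 30 and EXPB3 from 135 ± 3.71 to 67.5 ± 10.3. The call of XTH18 was lost without sps1 replicate 1 or 2 (0.0573 or 0.0572). The single rise, 0.60 for XTH33, was lost without the third wild type array (0.0597), the second (0.102), L17 replicate 2 (0.0562) and sps1 replicate 2 or 3 (0.114 or 0.1). In the brighter part of the probe sets the list's median was -0.46 and its camera adjusted p 0.155. The latter was 0.141 without the first and 0.0904 without the second wild type array, 0.0171 without the third, 0.0598 without L17 replicate 3, and 0.0576 or 0.0617 without sps1 replicate 1 or 2.

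PORB rose and HEMA2 fell in sps1 too, by log2 fold changes of 1.08 and -1.77, and HEME2 gave 0.58, a call lost without the second wild type array (0.0599) or sps1 replicate 2 or 3 (0.0597 or 0.0708). In the dark-inducible list SAG29 and MCCB gave 0.98 and 0.57, calls lost without the first or second wild type array or any sps1 replicate (adjusted p between 0.0538 and 0.0766), and without the third wild type array that list passed its test (camera adjusted p = 0.0281, and adjusted p = 0.579 with an estimated correlation), as it did with array weights (camera adjusted p = 0.0427). Of 6 flavonoid genes 1 rose and 1 fell, with log2 fold changes of 1.14 for UGT78D2 and -1.20 for UGT78D1, the latter call being lost without the second wild type array (0.0554) or sps1 replicate 1 or 3 (0.0656 or 0.0694). Of 3 light harvesting genes LHCB4.2 fell by 0.84 and LHCB4.3 gave 0.61, a call lost without the second wild type array (0.0605) or sps1 replicate 2 or 3 (0.0706 or 0.0625). GID1B, a gibberellin receptor, gave -0.77, a call lost with any array left out (0.0518 to 0.136). The auxin response gene GH3.3 gave -0.62, a call kept without the first wild type array or L17 replicate 3 and lost with any other left out (0.0549 to 0.111). Of 47 called members of fixed lists 25 lost their call with at least 1 array left out, 11 of them without the third wild type array.

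ATSPS4F, which encodes a sucrose phosphate synthase, was the one gene with SPS in its name that was measured here, and no link between it and the line named sps1 is given by the labels. Its signal was 40.5 ± 12 in sps1, 100.4 ± 25.3 in wild type and averaged 120.5 in L17 (SD, n = 3). The log2 fold change was -1.04 in sps1 against wild type (limma adjusted p = 0.0142) and -1.28 against L17 (limma adjusted p = 0.0107), while L17 against wild type gave 0.24 (limma adjusted p = 0.55). Without sps1 replicate 2 or 3 the adjusted p against wild type was 0.0532 or 0.057.

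In sps1 3325 probe sets changed against wild type, 1519 higher and 1806 lower, and 1568 changed at least 2-fold. At an unadjusted p under 0.05 there were 6465, and the arrays of the 2 lines were separate for 33.4% of probe sets, where chance gives 10%. The split between higher and lower depended on the scaling: centring each array on its median gave 3721 changed probe sets with 60.2% higher, against 45.7% as deposited, and moved the median log2 fold change of all probe sets from -0.01 to 0.10. Without sps1 replicate 2 or 3 the count was 2093 or 2087, and without the third wild type array 3406.

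Compared with each other, sps1 and L17 differed at 1560 probe sets, 714 higher and 846 lower in sps1. AT1G23960 was the largest difference, at 2122 ± 119 in sps1 and 4.94 ± 4.22 in L17 (SD, n = 3), a log2 difference of 6.69 ± 0.16 (SE, limma adjusted p = 6.19e-07). AT4G19240 read 568 in sps1 and 6.52 in L17, AT4G13860 334 and 7.91, AT4G15680, of the glutaredoxin family, 408 and 19.96, and AT1G65510 1467 and 142. AT4G19730, AT5G20460, AT1G05770, AT5G27750 and AGL87, a MADS box gene, were the remaining of the 10 largest rises, with log2 differences between 2.89 and 3.76. In the other direction AT5G23830 read 24.0 ± 26.6 in sps1 and 1532 ± 277 in L17, AT1G52100 16.6 and 897, and BGLU19, a beta-glucosidase, 40.4 and 1068. AT2G39210 read 177 against 2367, AT4G17470 81.2 against 1327, and AT4G19500 8.10 against 339. AT1G31550, AT5G41660, AT5G38030 and AT1G12400 had log2 differences between -3.64 and -3.22.

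The nuclear photosystem, ATP synthase and Rubisco list was higher in sps1 than in L17, with 3 of 6 members higher, 0 lower and a median log2 difference of 0.56 (camera adjusted p = 0.00026, and adjusted p = 0.28 with an estimated correlation). Adjusted over the list alone the count was also 3. PSAN read 3696 ± 311 against 2139 ± 352 and PSBY 6052 ± 258 against 3153 ± 691. The call of PSAN was lost without L17 replicate 2 or 3 (adjusted p = 0.0804 or 0.0642) or sps1 replicate 2 or 3 (0.0776 or 0.0679), and that of PSBY without L17 replicate 1 or 2 (0.0609 or 0.081) or sps1 replicate 1, 2 or 3 (0.0717, 0.0876 or 0.0767). The cell wall loosening list was lower in sps1 than in L17, with 3 of 9 members lower and 0 higher and a median of -0.71 (camera adjusted p = 2.14e-05, and adjusted p = 0.0979 with an estimated correlation). Adjusted over the list alone, 6 were lower. XTH19 read 1302 ± 208 against 2765 ± 475, a call lost without L17 replicate 2 or 3 (0.0674 or 0.0575) or sps1 replicate 2 (0.0575). EXPB1 read 254 against 518, a call lost without L17 replicate 1 or 3 (0.0518 or 0.06) or sps1 replicate 1 or 3 (0.0611 or 0.0511). The list written as markers of ungerminated seed was also lower in sps1 than in L17 (6 of 23 past the test, adjusted p = 0.33 with an estimated correlation), with a median between -0.20 and -1.55 depending on the setting. For the plastid-encoded list no difference between the lines was detected, with 1 member higher, 1 lower and a median of -0.18 (camera adjusted p = 0.39), though it was lower in sps1 without sps1 replicate 3 (camera adjusted p = 0.0122). CHLM, of chlorophyll synthesis, was higher by 0.85 on the log2 scale, a call kept with any array left out. LHCB4.1 (0.70), MCCB (0.70), UGT78D1 (-1.15), the mitotic kinase gene AUR1 (-0.65), nad4 (-1.13) and ccb452 (-0.65) also passed, with calls lost in 5 to 8 of the 9 fits that leave out 1 array (adjusted p between 0.0502 and 0.146). Of 17 called members of fixed lists 15 lost their call with at least 1 array left out. HYH, a bZIP transcription factor of light signalling, read 103 ± 2.54 in sps1 and 18.6 ± 14.4 in L17, a log2 difference of 1.89 (limma adjusted p = 0.0278) that did not pass without L17 replicate 2 or 3 (0.058 or 0.0672) or sps1 replicate 1, 2 or 3 (0.0857, 0.084 or 0.0829).

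At an unadjusted p under 0.05 this comparison gave 4644 probe sets, and the arrays were separate for 30.7% of the 22746 tested, where chance gives 10%. Median centring gave 1633 probe sets with 59.3% higher, against 45.8% as deposited. The third wild type array does not enter this difference but enters the shared estimate of spread. Without it the count was 2626, and with only these 2 lines in the fit it was 2074. Leaving out any 1 array of the 2 lines, which leaves 2 arrays against 3, lowered the count. It was 931, 719 or 914 without L17 replicate 1, 2 or 3, and 912, 830 or 807 without sps1 replicate 1, 2 or 3.

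**Figure D3:**
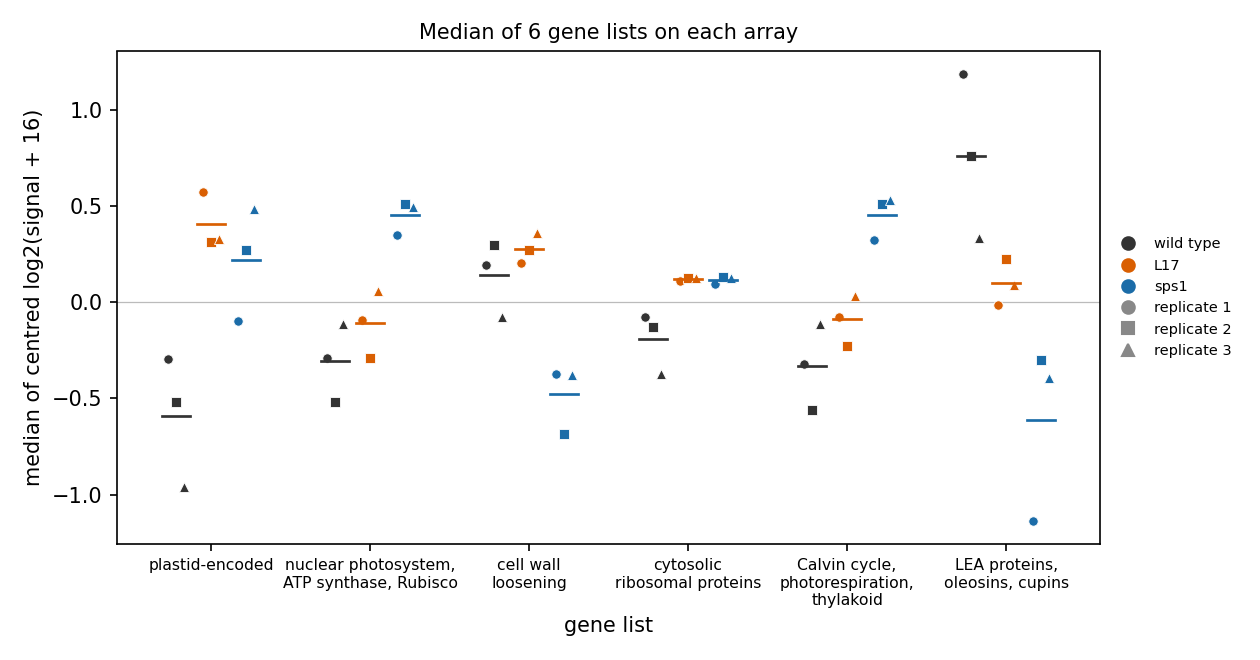
Median of 6 gene lists on each of the 9 arrays, after each gene's log2(signal + 16) was centred on its mean over all arrays. Points are single arrays, bars are means over the 3 arrays of a line, and the median of the nuclear photosystem list lay between 0.35 and 0.51 in sps1 and between -0.52 and -0.11 in wild type.

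Many probe sets changed the same way in both lines, 583 higher and 860 lower, while 44 changed in opposite directions. Lists of these lengths drawn independently would share 80.8 higher and 110 lower, and would have 189 in opposite directions. The 10 shared genes with the largest changes, AT5G45500, ZW9, AT3G55790, AT4G07820, AT3G47250, AT2G43590, CYP71B34, AT3G43740, AT5G26270 and AT5G05750, all fell. AT5G05750 went from 1708 ± 213 in wild type to 56.5 ± 13.9 in L17 and 61.6 ± 18.8 in sps1. Of these 10 genes ZW9 passed the test between L17 and sps1, with a log2 difference of -0.95 (limma adjusted p = 0.029). That call was lost with a pseudocount of 1 (adjusted p = 0.0632), without L17 replicate 1, 2 or 3 (0.0863, 0.107 or 0.0656) and without sps1 replicate 1 or 3 (0.0602 or 0.0574), while AT2G43590, with a log2 difference of -1.07 (limma adjusted p = 0.0974), passed without L17 replicate 2 (0.0271), among the brighter probe sets (0.0311) and with trended robust moderation (0.032). Log2 fold changes of the 2 lines correlated across probe sets at r = 0.69, against 0.50 in 100 simulations of unchanged lines that shared simulated wild type arrays, and their covariance was 0.273 against 0.0366, a difference of 0.237. The simulated arrays were drawn anew and do not hold the joint shift of the third wild type array. The simulated values may therefore understate what sharing the real wild type arrays gives. Both comparisons use the same 3 wild type arrays, which are too few to be split into parts of at least 2, so part of the overlap may come from them. Of the probe sets called the same way in both lines, 137 also differed between sps1 and L17. Without L17 replicate 1 or 2 the shared count of 1443 was 922 or 912.

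The remaining fixed lists did not pass their tests in any of the 3 comparisons, given here in the order L17 against wild type, sps1 against wild type and sps1 against L17. The camera adjusted p was 0.752, 0.795 and 0.39 for light harvesting, 0.921, 0.345 and 0.39 for tetrapyrrole and chlorophyll synthesis, and 0.871, 0.795 and 0.713 for flavonoid synthesis. It was 0.921, 0.795 and 0.461 for auxin response, 0.921, 0.795 and 0.638 for gibberellin, and 0.752, 0.166 and 0.39 for dark-inducible and senescence genes. For autophagy it was 0.752, 0.795 and 0.682, and for fatty acid beta-oxidation 0.793, 0.795 and 0.739. Root markers gave 0.921, 0.795 and 0.638, markers of dividing cells 0.752, 0.795 and 0.336, and abscisic acid and cold response 0.752, 0.795 and 0.682. Mitochondrion-encoded transcripts gave 0.752, 0.795 and 0.39, with 2 of 16 members up and 1 down in L17, and 2 up and 2 down in sps1. Among them cox1 rose by 1.67 in L17 and 1.55 in sps1 and ccb382 by 2.33 and 1.92 on the log2 scale, while ccb452 fell by 1.02 in sps1. The remaining fall, nad4L, gave -0.86 in L17, a call kept without sps1 replicate 2 or 3 and lost with any other array left out (adjusted p between 0.0723 and 0.157), and -0.87 in sps1, a call kept without sps1 replicate 2 and lost with any other left out (0.05 to 0.094).

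Some fixed lists had under 3 measured members and were not tested as lists. FHL, which carries phytochrome A into the nucleus, fell in both lines, from 414 ± 36.8 in wild type to 149 ± 29.2 in L17 (log2 fold change -1.39, limma adjusted p = 0.00693) and 167 ± 51.8 in sps1 (-1.28, limma adjusted p = 0.00804). UGT74B1, of indolic glucosinolate synthesis, fell by 2.40 in L17 on the log2 scale and gave -1.18 in sps1 (limma adjusted p = 0.043). The latter call held without the second wild type array or L17 replicate 2 and was lost with any other array left out (adjusted p between 0.0543 and 0.114). The clock gene GI had a log2 fold change of 0.61 in sps1 (limma adjusted p = 0.0478) and 0.37 in L17 (limma adjusted p = 0.22), and the former call held without the second wild type array alone (0.0496 there, 0.062 to 0.141 with another array left out). AT2G31790, of aliphatic glucosinolate synthesis, gave 1.17 in L17, a call kept without the third wild type array (0.00551) and lost with any other left out (0.0522 to 0.127), and 0.96 in sps1 (limma adjusted p = 0.0632), and BCAT4 of the same list gave 1.00 in L17 (limma adjusted p = 0.0502) and 0.81 in sps1. Against wild type, LYC gave log2 fold changes of 0.05 in L17 and 0.04 in sps1, EIN3 -0.32 and -0.03, GUT2 -0.28 and -0.30, PDF1.2 0.40 and 0.47, and THI2.1 0.40 and 0.49, none past the test. ATHSP22.0 gave -0.73 and 0.29, and the seed markers AT1G03890 and M17 gave 0.63 and 1.15, and -1.96 and -1.21, none past the test. HYH did not pass the test against wild type, with log2 fold changes of -0.71 in L17 and 1.17 in sps1.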

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

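The tests of neighbouring genes and of leaving out the third wild type array were set before their results were seen, and the count of losses against gains was chosen after.

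L17 and sps1 changed in opposite directions against wild type at 44 probe sets. Of these, 24 were higher in L17 and 20 higher in sps1, and 23 name 1 gene. BGLU19 had log2 fold changes of 1.53 in L17 and -2.77 in sps1, and AT4G17470 of 2.04 and -1.77. The transporter gene AT5G38030 gave 1.63 and -1.70, PDF1.4, a defensin, 1.24 and -1.15, and AT1G05770 -2.28 and 0.92. AT1G23960, lost in L17 and kept in sps1, had a log2 difference of 6.69 between the lines. Control probe sets that enter no comparison also differed: the ubiquitin 3' to 5' ratio was 2.32 in L17 and 2.49 in sps1, above the wild type arrays.

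Many of the largest changes were losses of signal. Of 90 probe sets changed at least 8-fold in L17, 72 were lower, 80% (exact binomial 95% interval 70.2 to 87.7), and in sps1 92 of 111 were, 82.9% (74.6 to 89.4), while sps1 against L17 gave 18 of 34, 52.9% (35.1 to 70.2). These intervals treat probe sets as independent, which they are not, so they may be too narrow. Both lines were compared with the same wild type arrays, so their 2 shares of losses are not independent observations. The third wild type array is argued against as the whole cause, since 100% of the 8-fold calls in either line stayed past the threshold without it, and 67 of 90 and 90 of 111 stayed at least 8-fold. It read over 2-fold above the other wild type arrays at 2146 probe sets and below at 692, which could add losses in both lines. The share of losses without this array was not counted. An excess of losses is what probe sets would show if the lines carried sequence from another strain that binds them less well, so a strain difference may contribute, but real loss of expression gives the same excess. Stretches of another genome would place genes of one kind side by side: among 62 genes classed as changed alike or differently in the 2 lines, 57.9% of neighbours shared their class, against 49.2% in shuffles (one-sided permutation p = 0.117), which leaves this open, as does an effect of what each line carries, which was not tested.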

How the results depend on the processing

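Probe sets called both here and under an alternative kept their sign under all the alternatives run (0 turned). This count says little about robustness, since it covers only probe sets past the threshold in both fits. Several alternatives, such as the stricter threshold, also left the log2 fold changes unaltered. With the replicate block 1013 probe sets differed between sps1 and L17 (1560 without it), and the block moved no other count by over 1.5 times. Deviations of same-numbered arrays from their line means correlated between -0.0795 and 0.0589, and not every array correlated best with its own number. With the block the cell wall loosening list did not pass in sps1 against wild type (camera adjusted p = 0.0541), and AT2G43590 passed between sps1 and L17 (adjusted p = 0.0393). Array weights gave 3048 for that comparison, and the fit of 2 lines gave 1611 for L17 against wild type and 2074 for sps1 against L17. A fold threshold left 1249, 1568, 776 and 692 probe sets for L17 against wild type, sps1 against wild type, sps1 against L17 and the shared set, and an adjusted p under 0.01 left 1024, 1474, 569 and 580, by construction. Leaving out single arrays gave 1437 to 2596, 2087 to 3406, 719 to 2626 and 912 to 1479 in the same order. Camera with an estimated correlation called 0 lists in L17 against wild type, 0 in sps1 against wild type and 0 in sps1 against L17, where the preset correlation called 1, 3 and 2, and fry called 1, 3 and 3, among them the markers of dividing cells in sps1 against L17 (0.0191). Of the lists added later fry called 13, 11 and 7 in that order, where camera called 2, 3 and 6. With an estimated correlation no added list was called either. Over the settings that change the values, arrays or threshold, 1419 repeats for named genes stayed as they were, called or not called, 12 lost a call and 4 gained one. The 1419 include genes with no call in the main setting, such as AT5G45500 in sps1 against L17. For called lists 310 repeats of camera at the preset correlation kept the call while 13 did not. These repeats do not cover camera with an estimated correlation, which ended the call of every list. In sps1 against L17 the estimate was below the preset 0.01 for histones (-0.0808), class III peroxidases (-0.0121) and serine carboxypeptidase-like proteins (-0.00618). A higher correlation between members therefore does not account for these lost calls. For the other called lists the estimate was above the preset, between 0.02 and 0.308. The level of PHYA was not run under any alternative. Signals near background limit the folds of the genes lost in a line, since 16.5% to 21.3% of probe sets on an array lay under the pseudocount of 16.

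The 3 counts of changed probe sets were set against the 10 splits of each comparison's 6 arrays, which are too few for a share under 0.05. In each comparison 1 split, the real one, gave as many: 2601, 3325 and 1560 probe sets, where the highest of the others gave 0, 0 and 0.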

Other observations

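The lists of the first 3 paragraphs were written after the annotation had been seen and before any comparison of lines, the tests of the third wild type array and of organelle labelling were chosen after the results were seen, and the test of plastid-encoded transcripts without that array was set before. Genes for Calvin cycle, photorespiration and thylakoid proteins were higher in sps1, with 11 of 20 members up and 1 down against wild type (camera adjusted p = 3.96e-08, and adjusted p = 0.244 with an estimated correlation) and 6 up and 0 down against L17 (camera adjusted p = 1.41e-08, and adjusted p = 0.131 with an estimated correlation). Of the 20, 9 also stand in the fixed photosynthesis lists. SBPASE, a Calvin cycle enzyme, rose from 372 ± 35.3 in wild type to 1493 ± 88.1 in sps1 (SD, n = 3). In L17 it read 1199 ± 245, and this list did not pass there (6 up, 1 down, camera adjusted p = 0.157). Cytosolic ribosomal protein genes were higher in both lines, with 15 up and 4 down of 112 in L17 (median 0.29, camera adjusted p = 3.52e-08, and adjusted p = 0.392 with an estimated correlation) and 16 up and 4 down in sps1 (median 0.29, camera adjusted p = 2.27e-06, and adjusted p = 0.437 with an estimated correlation). Without the third wild type array the medians were 0.21 and 0.22.

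The list of late embryogenesis abundant proteins, oleosins and cupins, written as markers of ungerminated seed, was lower in both lines. Its 2 members that also stand in the fixed seed list went opposite ways, and neither passed the test. AT1G03890 had log2 fold changes of 0.63 in L17 and 1.15 in sps1, and M17 of -1.96 and -1.21. The signals of AT1G03890 were low, at 8.15 ± 10.1 in wild type, 22.5 ± 17.1 in L17 and 36.0 ± 15.3 in sps1. M17 read 1108 ± 560, 513 ± 631 and 524 ± 334 in the same order (SD, n = 3). The directions of these 2 genes are therefore uncertain. Whether the lines differed in ungerminated seed itself was not tested. Of 23 members 4 fell in L17 (median -0.76, camera adjusted p = 0.00984, and adjusted p = 0.392 with an estimated correlation) and 10 in sps1 (median -1.26, camera adjusted p = 2.27e-06, and adjusted p = 0.244 with an estimated correlation), with 0 rising, and 6 were lower in sps1 than in L17 (camera adjusted p = 0.0012, and adjusted p = 0.33 with an estimated correlation). Its median moved with the setting: among the brighter probe sets it was -1.33 in L17 and -1.91 in sps1, and in sps1 against L17 it was -0.45, -1.04 with a pseudocount of 1, -0.20 with 64 and -1.55 among the brighter ones. With 64 it was -0.80 in sps1 against wild type. Without the first wild type array the list did not pass in L17 (camera adjusted p = 0.142). AT3G02480 read 4466 ± 179 in wild type, 2056 ± 389 in L17 and 627 ± 187 in sps1 (SD, n = 3), and AT3G17520 3225 ± 1380, 990 ± 56.1 and 201 ± 73.8. In sps1 against L17 class III peroxidases were lower, with 9 of 50 down and 1 up (camera adjusted p = 0.000884, and adjusted p = 0.0509 with an estimated correlation), as were expansins and xyloglucan endotransglucosylases, with 8 of 27 down and 1 up (camera adjusted p = 4.36e-05, and adjusted p = 0.0509 with an estimated correlation), of which 9 stand in the fixed cell wall list. Histones (0 of 10 past the test, camera adjusted p = 0.0154) and serine carboxypeptidase-like proteins (2 of 29 lower, camera adjusted p = 0.0154) also passed there, with adjusted p = 0.116 and 0.113 with an estimated correlation. The histones did not pass without sps1 replicate 1 (camera adjusted p = 0.0565), nor the carboxypeptidases without L17 replicate 3 (camera adjusted p = 0.0529). The peroxidase AT4G36430 read 68.2 ± 8.35 in sps1 and 625 ± 132 in L17 (SD, n = 3).

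In the main setting the other added lists did not pass, given in the order L17 against wild type, sps1 against wild type and sps1 against L17. Their camera adjusted p was 0.0957, 0.479 and 0.294 for small heat shock proteins, 0.16, 0.525 and 0.355 for protein folding in the endoplasmic reticulum, and 0.157, 0.105 and 0.662 for UDP-glycosyltransferases. It was 0.736, 0.407 and 0.355 for tau glutathione S-transferases, 0.141, 0.109 and 0.722 for SWEET transporters, and 0.168, 0.912 and 0.355 for beta-glucosidases. Trichome birefringence-like proteins gave 0.85, 0.494 and 0.352, cytochrome P450 0.136, 0.249 and 0.722, AGAMOUS-like genes 0.651, 0.91 and 0.722, and tubulins 0.0586, 0.105 and 0.355. Without the third wild type array the small heat shock proteins were higher in sps1 than in L17 (2 of 8 up, camera adjusted p = 0.0031, and adjusted p = 0.37 with an estimated correlation), and they passed there with these 2 lines alone in the fit (0.00268). In L17 against wild type they passed without the second wild type array (0.019), as did tubulins (0.0281), which also passed with a pseudocount of 64 (0.0337). Class III peroxidases, at 0.0648 in sps1 against wild type, passed without the third wild type array (0.0107, and adjusted p = 0.0915 with an estimated correlation), with median centring (0.0335), quantile normalization (0.0388) and array weights (0.0225). Among the brighter probe sets 7 added lists passed in L17 and 5 in sps1 against wild type, where all probe sets gave 2 and 3. Of the SAUR list 1 member was named here, AT2G18010, with a log2 fold change of 0.72 in L17 and 0.83 in sps1 (limma adjusted p = 0.055 and 0.0273).

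The third wild type array stood apart in 2838 probe sets. A label exchanged with another line is argued against: of 37 probe sets at least 8-fold lower in both lines, chosen without this array, 100% lay nearer on it to the other wild type arrays than to the lines. Degraded RNA is left open. Of the 3 control ratios 1, that of actin, lay above the other 8 arrays. The top of the ubiquitin range came from L17 and sps1, so that ratio could not decide. Among the wild type arrays this one was highest for actin (3.094 against 2.301 and 2.562) and ubiquitin (1.959 against 1.797 and 1.805), but not for GAPDH (1.408 against 1.309 and 1.533). The dap control probe sets target a bacterial transcript, not one of the seedlings. Their 3' to 5' ratio was 8.841 on this array, against 4.313 to 6.191 on the other 8, and cannot show whether seedling RNA was degraded. Stress of these seedlings before or at harvest is a candidate explanation: small heat shock proteins read 2.75 higher on the log2 scale (median of 8) than on the other wild type arrays, above all of 10000 random lists of like signal, and AT1G52560, Fes1A and the calmodulin-like gene CML37 were among the 10 largest differences, by 6.38, 5.11 and 4.88. Other lists were extreme in the same test. The plastid-encoded (-0.57), cytosolic ribosomal (-0.29) and late embryogenesis abundant (-0.70) lists lay at percentile 0 of the random lists, and the Calvin cycle list (0.25) at 99.97. The random lists ignore that members of a list change together, so this test does not single out stress. The labels name no treatment.

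Plastid-encoded transcripts were higher in both lines, a call lost with an estimated correlation (adjusted p = 0.924 in L17 and 0.457 in sps1). The third wild type array alone is argued against as the cause. Without it the medians were 0.92 in L17 and 0.538 in sps1, with 23 and 16 members up (adjusted p = 0.918 and 0.579 with an estimated correlation). With it the sps1 median was 0.792. The rise in sps1 was uneven. After centring, the list's median was -0.0955, 0.271 and 0.485 on the sps1 arrays. It was 0.577, 0.316 and 0.328 on the L17 arrays, and -0.292, -0.52 and -0.961 on the wild type arrays. Organelle RNA labelled to a different extent could raise plastid-encoded signals. Mitochondrion-encoded transcripts moved less, with the plastid median higher by 0.741 in L17 and 0.835 in sps1 (0.657 and 0.393 without the third wild type array), but their own spread (SD 0.842 and 0.797 over 16 members) keeps this open. An effect of the lines stays open and was not tested.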
